A study of Sparus aurata with 25 samples.

How the data were processed

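Total RNA from the brain of gilthead sea bream (Sparus aurata), a marine teleost, was labelled with a single dye and hybridised to Agilent oligonucleotide arrays, 1 sample per array. The 25 arrays fall into 5 groups of 5: untreated controls, fish kept with the solvent DMSO, and fish exposed to acetaminophen (APAP), carbamazepine (CBZ) or atenolol (AT). Exposure to a drug or DMSO lasted 28 days per the labels. The labels state that DMSO was kept at 0.0005% in the drug tanks. They give no DMSO percentage for the DMSO group and no day for the controls. Drug concentrations are left out here because the unit in the labels could not be checked.

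The scanner images were turned into spot values with Agilent Feature Extraction, version 9.5 per the submitters' processing notes and 9.5.1.1 per the file headers. The scanner intensity values used are the processed signal, mean signal and local background of each spot as deposited. Each array has 14141 spots, of which 536 are controls and 13605 carry a probe of 60 bases. The authors also deposited a table of processed signal values for the same arrays. Its log2 values correlated with the scanner values of the same array at r between 0.996 and 1.00, and the column medians lay between 64.0 and 79.5. It holds values for 13745 spots. The spread of its upper quartile between arrays was 0.0836 on the log2 scale, against 0.341 in the scanner values, so it had been scaled between arrays, by a method not given in the sources used here.

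The main values are log2 of the processed signal minus the 75th percentile of that array. Control spots were left out, and 67 values of spots marked as non-uniform or as population outliers were treated as missing. Probes were kept when well above background on at least 4 of the 5 arrays of at least 1 group, which left 10383. The linear model of limma 3.58.1 in R 4.3.3 was fitted with 1 coefficient per group to all 25 arrays, so that the groups share 1 estimate of the spread, followed by empirical Bayes moderation and Benjamini-Hochberg adjustment within each comparison. A probe is said to differ when its adjusted p is under 0.05. All 10 pairs of groups were compared, together with a moderated F-test over the 5 groups. These choices and most of the alternatives were fixed before the data were examined. Permutational analysis of variance used vegan 2.7.1 with 9999 permutations.

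The labels name no tank, fish or pool behind a sample. P-values therefore measure only the spread between these samples, which may be partly technical. The number of arrays limits the precision: the median standard error of a difference between 2 groups was 0.237 on the log2 scale. The fit was tested on simulated data for each comparison, with 200 of 10383 probes changed. For the comparison of APAP with control it recovered 56.7% of probes changed 2-fold and 81.8% of those changed 4-fold.

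The file headers place the 25 arrays on 4 slides, each scanned once. Slide 1 held 2 DMSO, 3 APAP and 3 CBZ arrays. Slide 2 held 2 control and 3 AT arrays. Slide 3 held 2 control, 1 DMSO, 2 APAP, 1 CBZ and 2 AT arrays. Slide 4 held 1 control, 2 DMSO and 1 CBZ arrays. Slide was therefore tried as a fixed and as a random block, and differences were also taken within each slide that holds both groups. The counts within a slide come from a fit of all arrays with 1 mean per group and slide, so that a side with 1 array takes its spread from the other arrays. The fit of slide 3 alone takes its spread from that slide.

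No probe was given a gene name. Descriptions and probe names were used for this, and the probe sequences were not searched. The description of each probe in the files is unknown, and 0 of the 13605 probe names matched the reference gene table of 32006 genes. The tests of gene lists planned before the data were examined could not be run, nor could the planned rule for named genes. In its place, each comparison names up to 2 probes that were higher and up to 2 that were lower. These have the largest absolute log2 difference among probes that differ and that are well above background on at least 4 of 5 arrays of the higher group. That rule was written once the probe names had been seen and before any test was run. Probes named only by a database number were not named.

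A probe that was not well above background on any array of the lower group has only a bound there. Its fold is then given as at least the higher group's mean over the dim group's mean, over all arrays or those of a slide, where each dim array takes the higher of the probe's own signal and the lowest signal among probes well above background. Alternatives tried were quantile normalization, normexp background correction with an offset of 50, the deposited table, other filters on dim probes, blocks for replicate number or slide, array weights, a fold of at least 1.5, fits of the 2 groups alone, control and DMSO together as 1 comparator, and leaving out each array in turn. Several more were chosen after seeing the data: leaving out slide 2, slide 2 or slide 3 alone, slide and row on the slide as a joint block, no scaling between arrays, cyclic loess with the trend in GC content removed, a contrast of APAP and CBZ with control and DMSO, the AT arrays split between APAP and CBZ, and an intensity trend with a robust prior.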

Results

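Brain transcript levels were measured on 25 one-colour arrays, 5 for each of untreated control, DMSO, acetaminophen (APAP, an analgesic), carbamazepine (CBZ, an anti-epileptic) and atenolol (AT, a beta-blocker). The comparisons ask which transcripts of the brain differ after exposure to each drug. The files pair no probe with a gene name, so differences are given by probe. Between 8379 and 11964 of the 13605 probes were well above background on an array. The upper quartile of the processed signal ran from 316 to 841. Pairs of arrays correlated across probes at a median r of 0.959 within a group and 0.947 between groups. Pairs from different groups on the same slide had a median r of 0.961, and those on different slides 0.944. Within a group the median r was 0.959 both for the 15 pairs on the same slide and for the 35 on different slides.

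The first principal component held 31.0% of the variance and the second 23.6%. The 5 arrays of slide 2, which are 2 controls and 3 AT arrays, lay between -82.5 and -20.0 on the second component, below the other 20 arrays, which lay between -17.2 and 66.0. The spike-in probe E1A_r60_3, a dim one, had a log2 signal of 3.41 ± 0.52 (SD, n = 5) on slide 2 and 1.07 ± 0.29 (SD, n = 20) on the other slides, without overlap. The 2 other spike-ins examined overlapped between slide 2 and the other slides. The bright E1A_r60_1 stood at 16.55 ± 0.47 (SD, n = 5) there and 16.33 ± 0.66 (SD, n = 20) elsewhere. E1A_r60_a104 ran from 1.26 to 1.89 on slide 2 and from 0.78 to 1.79 elsewhere. In a permutational analysis of variance, slide alone accounted for 31.4% of the variation between arrays (permutation p = 0.0002) and group alone for 22.6% (permutation p = 0.0687). With slide taken into account and arrays permuted within slides, group accounted for 11.8% (permutation p = 0.618).

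**Figure D1:**
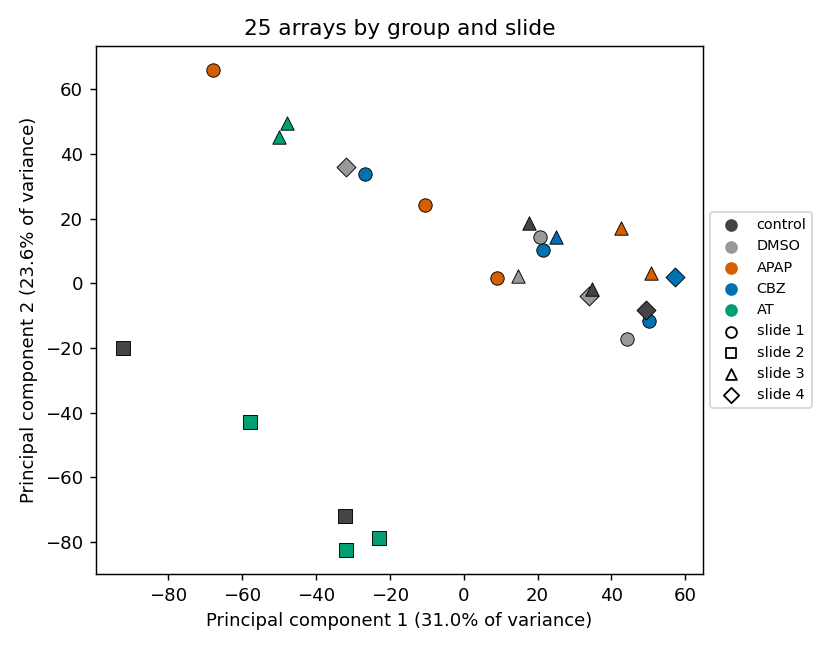
Each point is 1 of the 25 arrays on the first 2 principal components of the log2 levels, with colours for the 5 groups and symbols for the 4 slides. The 5 arrays of slide 2 lie at -20.0 or lower on the second component.

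DMSO was compared with control as the solvent alone. By limma, 0 of 10383 probes differed, and 586 had an unadjusted p under 0.05. The 95% interval of the difference lay within 4-fold for 89.1% of probes. With slide as a block the count was again 0. Within single slides it was 4 on slide 3, with 1 DMSO array, and 0 on slide 4, with 1 control array. Across probes, the log2 difference of DMSO from control correlated with that of APAP from control at r = 0.634 and with that of CBZ from control at r = 0.701, where the controls are shared and unchanged groups simulated that way gave 0.499. The simulation took no account of slide, and slide 2 held 2 controls but no DMSO, APAP or CBZ array. The differences of DMSO, APAP and CBZ from control also rose with mean probe level, at Spearman rho 0.545, 0.467 and 0.413. Values above 0.499 therefore do not show a response to DMSO. For the probes that differed from control in APAP or CBZ, DMSO lay from control by a median log2 difference of 0.28 and 0.30 in the direction of the drug. Those probes were picked against the same control arrays, so medians above 0 can follow from selection alone. No value for an unchanged group was computed for these medians.

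SAPD21854_1 was higher in APAP than in control, with a log2 level of 0.08 ± 0.32 (SD, n = 5) against -1.50 ± 0.38 (SD, n = 5). The log2 difference was 1.59 with a standard error of 0.22 (limma adjusted p = 0.00444), and the arrays of the groups did not overlap. Its probe sequence is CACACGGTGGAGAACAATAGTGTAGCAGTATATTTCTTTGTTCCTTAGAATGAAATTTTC. SAPD12045_1S was 2.75-fold higher in APAP (log2 difference 1.46, adjusted p = 0.0484). SAPD10387 was lower in APAP than in control, with a log2 difference of -2.02 (adjusted p = 0.0484), where 2 of 5 APAP arrays were well above background and the other values lay near it. SAPD20567 was at least 1.52-fold lower (adjusted p = 0.0484), since none of its APAP arrays was well above background. On slide 3, which holds 2 arrays of each group, the log2 differences were 1.30 for SAPD21854_1 and 1.38 for SAPD12045_1S. There SAPD10387 was at least 2.18-fold lower in APAP, and no fold could be given for SAPD20567. In fits with 1 array left out, SAPD21854_1 passed the threshold in 10 of 10, and SAPD12045_1S, SAPD10387 and SAPD20567 in 1 of 10 each. The adjusted p with slide as a block was 0.20, 0.454, 0.574 and 0.454 in that order.

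In all, 56 probes differed between APAP and control, 25 higher and 31 lower in APAP, with a median absolute log2 difference of 0.88. An unadjusted p under 0.05 was found for 1986 probes. With slide as a block the count was 0, while all 56 probes kept their sign, with a median log2 change of 0.68 and a median standard error that went from 0.19 to 0.20. Within slide 3 the count was 1. Against DMSO the same 56 probes all kept their sign, with a median log2 difference of 0.51 in that direction, and 1 of them differed. These probes were picked on the same APAP arrays, so kept signs and such a median can follow from selection alone. No value for unchanged groups was computed for them. The deposited table gave 394, of which 241 were higher and 153 lower. Leaving out 1 array moved the count by over 1.5 times for 9 of 10 arrays: it was 1 without APAP 1, APAP 5, control 2, control 3 or control 5, 2 without APAP 2, 20 without control 4, 21 without control 1 and 105 without APAP 3.

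SAPD21854_1 was also higher in CBZ than in control, at -0.15 ± 0.21 (SD, n = 5). Its log2 difference was 1.35 with a standard error of 0.22 (limma adjusted p = 0.0129). SAPD09705_1 was 2.45-fold higher in CBZ (log2 difference 1.29, adjusted p = 0.0345). SAPD24719_1 was lower in CBZ, with a log2 difference of -1.43 (adjusted p = 0.0454). SAPD06170_1 was at least 1.81-fold lower (adjusted p = 0.0427), as no CBZ array measured it well above background. Within slide 3 the log2 differences were 1.21 for SAPD21854_1, 1.41 for SAPD09705_1 and -1.45 for SAPD24719_1, and within slide 4 they were 1.45, 0.52 and -1.81. SAPD06170_1 was at least 1.87-fold lower on slide 4, and no fold could be given for it on slide 3. In fits with 1 array left out, SAPD21854_1 passed the threshold in 10 of 10, SAPD09705_1 in 3, SAPD06170_1 in 1 and SAPD24719_1 in 0. SAPD24719_1 had a limma adjusted p of 0.103 with quantile normalization and 0.0664 with the deposited table. The adjusted p with slide as a block was 0.320 for SAPD21854_1 and SAPD06170_1, 0.375 for SAPD09705_1 and 0.552 for SAPD24719_1.

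Between CBZ and control 84 probes differed, 50 higher and 34 lower in CBZ, with a median absolute log2 difference of 0.83, and 1890 had an unadjusted p under 0.05. The count was 0 with slide as a block, while all 84 probes kept their sign, with a median log2 change of 0.72 and a median standard error that went from 0.18 to 0.20. It was 8 within slide 3, from 1 CBZ array, and 61 within slide 4, from 1 array of each group. Against DMSO the 84 probes all kept their sign, with a median log2 difference of 0.51 in that direction, and 0 of them differed by limma. Selection on the same CBZ arrays alone can give kept signs and such a median, and no value for unchanged groups was computed. Leaving out 1 array moved the count against control by over 1.5 times for 9 of 10 arrays: it was 6 without CBZ 4, 11 without control 5, 12 without CBZ 3, CBZ 5 or control 3, 16 without control 2, 31 without CBZ 2, 33 without control 4 and 47 without CBZ 1.

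Among the probes that differed from control, 37 were shared by APAP and CBZ, each in the same direction. Independent lists of those sizes would share 0.222, a value that leaves out the shared control arrays. The log2 differences of the 2 drugs correlated across probes at r = 0.71, where probes are not independent replicates. Unchanged groups simulated against shared controls gave a median r of 0.499. The covariance was 0.191 against a simulated 0.107. With the control arrays split between the drugs in 20 ways, the median r was 0.180, from -0.174 to 0.621, and 0 probes were shared. That count came from fits of 1 drug with part of the control arrays alone. A fit of the 2 groups alone gave 1 for APAP against control even with all their arrays. Few probes could therefore be shared whatever the cause, and the count does not decide. The simulation took no account of slide, and 3 APAP and 3 CBZ arrays were on slide 1, which held no control. Against DMSO the drugs correlated at r = 0.496 against a simulated 0.499, with a covariance of 0.0762 against 0.107 and a median r of 0.0018 with the DMSO arrays split.

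SAPD31433 was lower in AT than in control, at 2.78 ± 0.36 (SD, n = 5) against 3.94 ± 0.21 (SD, n = 5), a log2 difference of -1.16 with a standard error of 0.18 (limma adjusted p = 0.0123). Its sequence is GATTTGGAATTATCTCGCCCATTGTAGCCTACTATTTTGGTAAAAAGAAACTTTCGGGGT. SAPD31308 was lower by the same test, at 2.69 ± 0.28 against 3.84 ± 0.25 (SD, n = 5 each), a log2 difference of -1.15 (adjusted p = 0.0211). Its sequence is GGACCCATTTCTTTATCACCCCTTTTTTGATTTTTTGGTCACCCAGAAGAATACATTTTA. Levels of the 2 probes lay close on most arrays, such as 2.63 and 2.55 on AT 1 and 4.14 and 3.96 on control 2. The gap was widest on CBZ 3, at 3.52 and 3.08. They may not be independent results, as the transcripts behind them were not identified. On slide 2 the log2 differences were -1.36 for SAPD31433 and -1.30 for SAPD31308, and on slide 3 they were -0.94 and -0.89. With slide as a block SAPD31433 stood at -1.17 (adjusted p = 0.0456) and SAPD31308 at -1.13 (adjusted p = 0.0532). Both had an adjusted p of 0.213 with slide and row as a joint block, 0.274 without slide 2, 0.0576 with quantile normalization and 0.0659 with the deposited table. In fits with 1 array left out they passed the threshold in 5 and 4 of 10.

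Between AT and control 3 probes differed, all lower in AT, and 923 had an unadjusted p under 0.05. With slide as a block 2 differed. Within slide 2 the count was 4, all higher in AT, and within slide 3 it was 0. A fit of slide 3 alone gave 209, of which 198 were higher and 11 lower in AT. These were other probes: 0 of the 3 probes of all arrays were among them. On slide 3 both AT arrays lay in row 1, as did control 5, while control 4 lay in row 2. Leaving out 1 array moved the count of all arrays by over 1.5 times for 7 of 10 arrays: it was 0 without AT 1, AT 2, control 1 or control 3, 1 without control 2, 7 without AT 5 and 16 without AT 3. Against DMSO the 3 probes kept their sign, with a median log2 difference of 0.71 in that direction, and 0 of them differed. DMSO itself lay from control by a median log2 difference of 0.43 in the direction of AT. Selection on the same arrays can add to both medians, and no value for unchanged groups was computed. SAPD31433 stood at 3.48 in DMSO, 3.37 in APAP and 3.48 in CBZ, between its levels in AT and control.

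**Figure D2:**
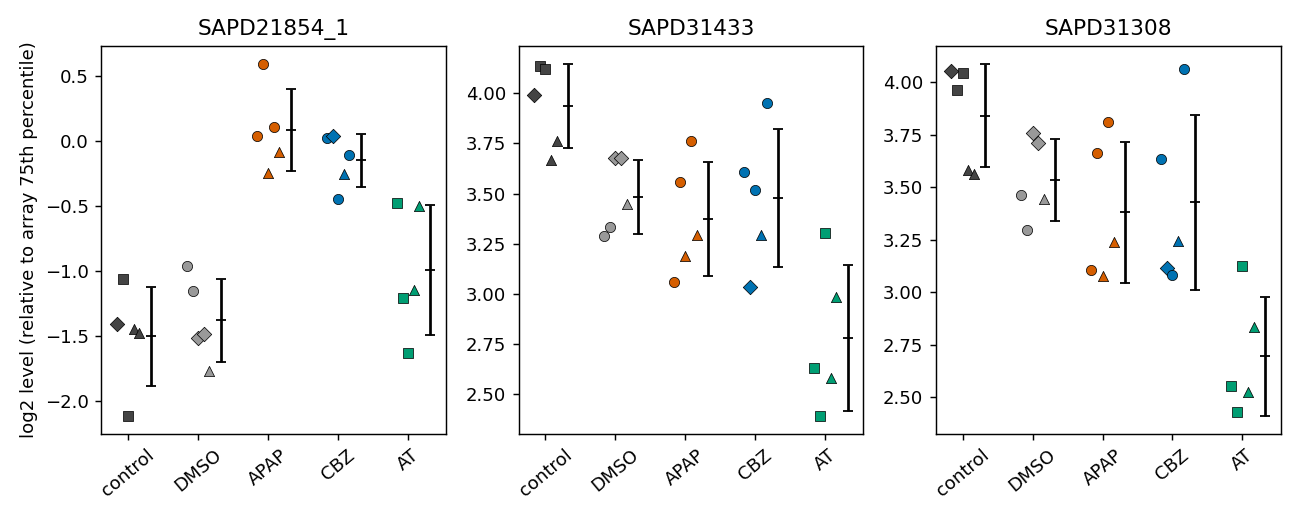
Log2 levels of 3 probes relative to the 75th percentile of the array, in each of the 5 groups, 1 point per array, with circles for slide 1, squares for slide 2, triangles for slide 3 and diamonds for slide 4, and bars give the mean and SD of 5 arrays. SAPD21854_1 lay at -0.45 or higher on the 10 APAP and CBZ arrays and at -0.96 or lower on the 10 control and DMSO arrays.

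The comparisons with DMSO set each drug against its solvent, whose dose in the DMSO group the labels do not give. SAPD21854_1 was the 1 probe that differed between APAP and DMSO, with a log2 difference of 1.46 and a standard error of 0.22 (limma adjusted p = 0.0152). Within slides 1 and 3 its log2 difference was 1.31 and 1.61, and with slide as a block it was 1.46 (adjusted p = 0.0537). An unadjusted p under 0.05 was found for 821 probes. With 1 array left out the count was 0 without APAP 1, APAP 2, APAP 4, DMSO 3, DMSO 4 or DMSO 5, 2 without DMSO 2, 3 without DMSO 1 and 4 without APAP 3.

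Between CBZ and DMSO 0 probes differed by limma, with 727 at an unadjusted p under 0.05. SAPD21854_1 had a log2 difference of 1.23 there (adjusted p = 0.167). Slide as a block gave 0, array weights gave 680, and leaving out DMSO 2 gave 2. The count was 0 within slide 1. It was 4 within slide 3, from 1 array of each group, and 122 within slide 4, from 1 CBZ array and 2 DMSO arrays.

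SAPD00498_1 was higher in AT than in DMSO, at -1.59 ± 0.20 against -2.38 ± 0.22 (SD, n = 5 each). The log2 difference was 0.79 with a standard error of 0.13 (limma adjusted p = 0.0327), on slide 3 it was 0.75, and with slide as a block 0.61 (adjusted p = 0.999). It passed the threshold in 5 of 10 fits with 1 array left out. This was the 1 probe that differed, and 1753 had an unadjusted p under 0.05. With slide as a block 0 differed, and within slide 3, with 1 DMSO array, the count was 2. With 1 array left out the count was 0 without DMSO 1, DMSO 2, DMSO 4, DMSO 5 or AT 1, 2 without AT 2 or AT 4, 4 without AT 3 and 9 without AT 5.

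The drugs were also compared with each other. Between APAP and CBZ 0 probes differed by limma, and 195 had an unadjusted p under 0.05. The 95% interval lay within 4-fold for 92.0% of probes. Slide as a block gave 0. Within slide 1, with 3 arrays of each, the count was 0, and within slide 3, with 1 CBZ array, it was 12.

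SAPD24427 was at least 1.45-fold higher in APAP than in AT (limma adjusted p = 0.0104), as no AT array measured it well above background. SAPD22030_1 had a log2 difference of 2.72 (adjusted p = 0.0486), where 1 of 5 AT arrays was well above background, the other values lay near it, and arrays overlapped between the groups. SAPD13147_1 was at least 3.42-fold lower in APAP than in AT (adjusted p = 0.0408). That bound rests on slide 2, where SAPD13147_1 had log2 levels of -2.96 to -2.46 in AT and of -3.01 and -2.99 in control, against -5.49 and -6.05 in AT on slide 3. With slide as a block its adjusted p was 0.557. SAPD21073_1 was lower with a log2 difference of -3.73 (adjusted p = 0.0418), where 1 of 5 APAP arrays was well above background, the other values lay near it, and arrays overlapped between the groups. On slide 3 SAPD24427 was at least 1.65-fold higher and SAPD21073_1 at least 28.4-fold lower in APAP. No fold could be given there for SAPD13147_1. SAPD21073_1 had log2 levels on slide 2 of -4.91 to -3.11 in AT and of -4.84 and -3.75 in control. On slide 3 it stood at -1.11 and 0.29 in AT, -5.42 and -6.41 in control and -3.10 on DMSO 5. It reached -1.33 on DMSO 3 of slide 4. Of 10 fits with 1 array left out, SAPD24427 passed the threshold in 10, SAPD21073_1 in 4, and SAPD22030_1 and SAPD13147_1 in 2 each. The adjusted p with slide as a block was 0.275 for SAPD24427, 0.605 for SAPD22030_1 and 0.387 for SAPD21073_1. With normexp background correction SAPD24427 and SAPD22030_1 took the other sign, at -0.32 and -0.17.

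Between APAP and AT 503 probes differed, 244 higher and 259 lower in APAP, with a median absolute log2 difference of 0.84, and 2837 had an unadjusted p under 0.05. Quantile normalization gave 928 higher and 479 lower, cyclic loess with the GC trend removed 716 and 430, normexp 2 and 0, and no scaling 14 and 1. The count was 0 with slide as a block, while all 503 probes kept their sign, with a median log2 change of 0.58 and a median standard error that went from 0.20 to 0.23. These probes were picked on the same arrays, so kept signs and such a median can follow from selection alone. The count was 3 within slide 3 and 11 without slide 2, while a fit of slide 3 alone gave 411, of which 48 were higher and 363 lower. On slide 3 the AT arrays lay in row 1 and the APAP and CBZ arrays in row 2, so differences from AT there are also differences between rows. The dim spike-in probe E1A_r60_3 ran from 0.75 to 0.84 in row 1 and from 1.15 to 1.72 in row 2. E1A_r60_a104 ran from 0.81 to 0.94 in row 1 and from 1.22 to 1.79 in row 2. The bright E1A_r60_1 overlapped, at 15.51 on DMSO 5 and 17.04 on AT 4 in row 1 and 16.54 on APAP 3 in row 2. Leaving out 1 array moved the count of all arrays by over 1.5 times for 7 of 10 arrays: it was 116 without APAP 5, 145 without AT 1, 178 without APAP 2, 240 without APAP 4, 258 without AT 3, 1241 without AT 4 (276 higher, 965 lower) and 1388 without AT 5 (329 higher, 1059 lower).

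SAPD04273_1 was higher in CBZ than in AT, with a log2 difference of 1.97 (limma adjusted p = 0.00773), where 3 of 5 AT arrays were well above background. SAPD18721_1 was at least 1.24-fold higher (adjusted p = 0.0320), since no AT array measured it well above background. SAPD32962_S was lower in CBZ, with a log2 difference of -4.30 (adjusted p = 0.0105), and SAPD13697_1 with one of -4.28 (adjusted p = 0.0263). For each of the latter, 1 of 5 CBZ arrays was well above background and the other values lay near it. On slide 3, with 1 CBZ array, SAPD04273_1 had a log2 difference of 1.99 and SAPD18721_1 was at least 5.81-fold higher in CBZ. SAPD32962_S was at least 8.58-fold and SAPD13697_1 at least 6.37-fold lower there. On slide 2 the controls had log2 levels of -3.20 and -3.86 for SAPD32962_S and of -2.38 and -3.10 for SAPD13697_1, near those of AT, and the other controls ran from -7.37 to -6.11 and from -8.63 to -7.16. The adjusted p with slide as a block was 0.265 for SAPD32962_S, 0.462 for SAPD13697_1, 0.268 for SAPD04273_1 and 0.231 for SAPD18721_1. Of 10 fits with 1 array left out, SAPD04273_1 and SAPD32962_S passed the threshold in 10, SAPD18721_1 in 6 and SAPD13697_1 in 5. With normexp background correction SAPD04273_1 and SAPD18721_1 took the other sign, at -0.20 and -0.59.

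Between CBZ and AT 906 probes differed, 475 higher and 431 lower in CBZ, with a median absolute log2 difference of 0.84, and 2973 had an unadjusted p under 0.05. Quantile normalization gave 1306 higher and 641 lower, cyclic loess with the GC trend removed 977 and 520, normexp 3 and 0, and no scaling 1160 and 60. The count was 0 with slide as a block, while all 906 probes kept their sign, with a median log2 change of 0.59 and a median standard error that went from 0.21 to 0.25. Selection of these probes on the same arrays can by itself give kept signs and such a median. The count was 7 within slide 3 and 72 without slide 2, while a fit of slide 3 alone gave 74, of which 8 were higher and 66 lower. Leaving out any of the 10 arrays moved it by over 1.5 times: it was 220 without AT 1, 305 without CBZ 5, 311 without CBZ 4, 409 without CBZ 3, 467 without CBZ 2, 501 without CBZ 1, 530 without AT 3, 574 without AT 2, 1413 without AT 4 (419 higher, 994 lower) and 1585 without AT 5 (504 higher, 1081 lower). Of the probes that differed, 384 were shared with the comparison of APAP with AT, each in the same direction, where the AT arrays are common to both. Independent lists would share 21.9, a value that leaves out the shared arrays. With the AT arrays split between the drugs in 20 ways, a median of 0 probes was shared, from 0 to 36. Those counts came from fits of 1 drug with part of the AT arrays alone. A fit of the 2 groups alone gave 0 for APAP against AT even with all their arrays. Few probes could therefore be shared whatever the cause, and the count does not decide. The log2 differences correlated at r = 0.865 against a simulated 0.499, and with the AT arrays split at a median r of 0.631, from 0.0370 to 0.715. Slide was left out of the simulation, although 3 AT arrays were on slide 2 and 3 APAP and 3 CBZ arrays on slide 1. Shared slides may therefore account for part of these correlations.

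**Figure D3:**
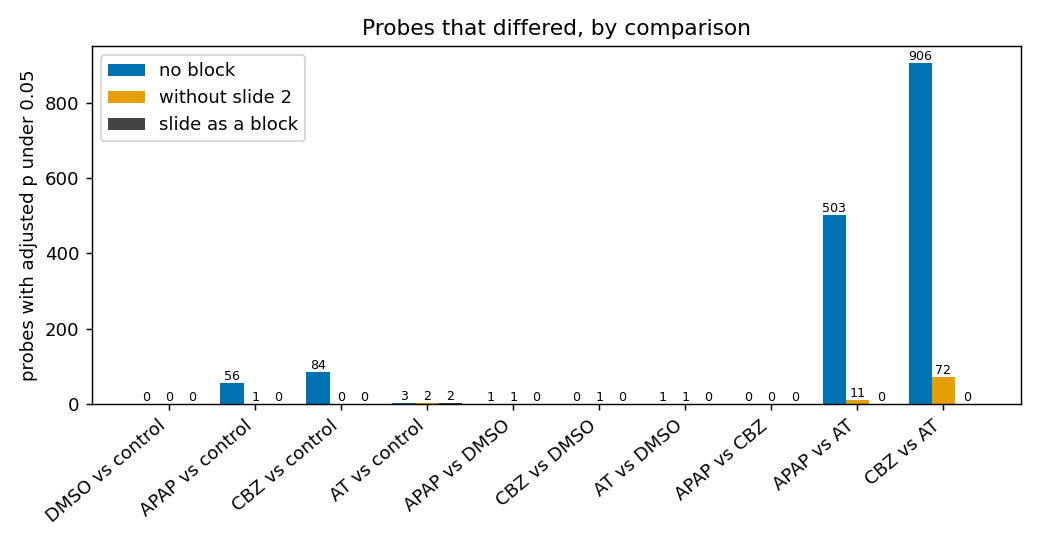
Number of probes with an adjusted p under 0.05 in each of the 10 comparisons, with all arrays and no block, without slide 2, and with slide as a block. Numbers above the bars give the counts, which for CBZ against AT were 906, 72 and 0.

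Over the 5 groups together, the moderated F-test found 281 probes, with 2344 at an unadjusted p under 0.05. The count was 0 with slide as a block and 2 without slide 2. Leaving out 1 array moved it by over 1.5 times for 10 of 25 arrays: it was 116 without CBZ 5, 117 without AT 1, 130 without APAP 5, 138 without CBZ 4, 143 without CBZ 3, 168 without CBZ 1, 175 without APAP 2, 176 without control 3, 468 without AT 5 and 513 without DMSO 1.

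Probe properties moved with several differences. The log2 difference correlated with the GC content of the probe, across probes, at a Spearman rho of -0.371 for APAP against control, -0.376 for CBZ against control, -0.412 for DMSO against control and 0.0387 for AT against control. It was -0.324 for APAP against AT, -0.298 for CBZ against AT and 0.304 for AT against DMSO. Probes that were higher in CBZ than in control had a median GC content of 35.0%, those that were lower 45.0%, and all probes tested 43.3%.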

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

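All tests of explanations below, the counts over other splits included, were chosen or written down only after the results they bear on had been seen. Some were also revised on sight of their outcome. The slide test of the first pattern at first read only the correlation of 0.766 and counted in favour of slide batch, and it was then made to need a loss of change with slide as a block as well, which left it open. The slide test of the second pattern at first read the change without slide 2, where the median log2 change was 0.74 for CBZ and 0.77 for APAP with 0 and 1 probes called, and was replaced by the block. The slide test of the third pattern was pooled over slides with a permutation, and an adjustment over all probes and the test of row on the slide were added last.

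In 8 of 125 groups of 5 values, 1 array lay far from the other 4, where chance gives about 6.25. Control 3 had a log2 signal of 16.06 for the spike-in E1A_r60_1, against 16.42 to 16.56 in the other controls. DMSO 3 had an upper quartile signal of 841, against 444 to 549. CBZ 3 lay apart for SAPD09705_1 at -3.02, for SAPD32962_S at -5.37 and for SAPD13697_1 at -4.51, above the other CBZ arrays each time. DMSO 3 lay apart for SAPD32962_S at -3.99, AT 4 for the same probe at -1.60, and APAP 1 for SAPD13697_1 at -2.44.

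Other splits of the same arrays into groups of 5 were fitted in the same way, 100 per comparison with the real one included. For APAP against control 2 of 100 gave at least the 56 probes of the real split, with 64 as the highest other. For CBZ against control, APAP against AT and CBZ against AT 1 of 100 did, with 0, 113 and 6 as the highest others against 84, 503 and 906. Over the 5 groups 3 of 100 gave at least 281, with 1115 as the highest other. Each of these 5, taken singly, argues against chance alone at the level of 5 in 100, but not against slide. No correction was made for the number of split tests, so chance is not excluded over them all. Over the 5 groups, group alone had a permutation p of 0.0687 in the permutational analysis of variance. For AT against control 6 of 100 splits gave at least 3 probes, and the highest gave 1775. That split set the 5 arrays of slide 2 against the rest, which points to a structure of the samples, and with slide as a block 2 probes differed. The highest other split of APAP and control set 5 arrays of slides 1 and 2 against 5 arrays of slides 3 and 4, and with slide as a block 0 probes differed between APAP and control. For APAP against DMSO 9 of 100 gave at least 1 probe, with 1041 as the highest, and for AT against DMSO 8 of 100 did, with 379. Counts so far above the real ones point to a structure of the samples, but these splits mixed slides and the cause was not tested. Chance is not excluded for AT against control or for these 2. For DMSO against control, CBZ against DMSO and APAP against CBZ the real count was 0 by limma, with 586, 727 and 195 at an unadjusted p under 0.05. All 100 splits reach a count of 0, so the splits say nothing there, and the highest others were 1, 1 and 2.

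The first pattern is the set of probes that differed between AT and CBZ or APAP. The trend with probe level and GC content is argued against as the whole cause, since 652 of the 906 probes of CBZ against AT were called again after both trends had been removed, as were 378 of the 503 of APAP against AT. Slide batch stays open. Slide 2 controls minus the other controls correlated across probes with AT minus CBZ at r = 0.766, against 0.521 for the highest and -0.730 for the lowest of the other splits of the controls. That difference took the sign of AT minus CBZ for 726 of the 906 probes (80.1%). With 1 mean per group and slide, 1189 probes differed between the controls of slides 2 and 3. Between the AT arrays of slides 2 and 3, 1534 differed. The count was 1 for APAP of slides 1 and 3 and 100 for DMSO of slides 1 and 4. With slide as a block, the median change between CBZ and AT went from 0.84 to 0.59 on the log2 scale and the median standard error from 0.21 to 0.25. The probes were picked on these arrays, so part of the kept change may be selection. A response to atenolol common to both slides stays open too, as AT minus control on slide 2 correlated with AT minus control on slide 3 at r = -0.337, and 6 of 60 relabellings within slides gave a value as low. Slide and drug may each contribute and cannot be told apart here, since 3 of the 5 AT arrays are on slide 2 and the other 2 lie in row 1 of slide 3, apart from the APAP and CBZ arrays in row 2. Those rows differed without overlap in the dim spike-in E1A_r60_3 (0.75 to 0.84 and 1.15 to 1.72). They also did in the number of probes well above background (9832 to 10538 and 8379 to 9414).

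The second pattern is the set of probes that differed between CBZ or APAP and control. A trend with probe level and GC content is argued against as the whole cause for CBZ, as 50 of its 84 probes were called again after both trends had been removed. For APAP it stays open, as 23 of 56 were called again, although 79 probes differed after the removal, all 56 kept their sign, and the median log2 change went from 0.88 to 0.72 and its median standard error from 0.19 to 0.16. Slide batch cannot be told apart from a response to the drug: with slide as a block the 84 probes kept 87.2% of their median change, from 0.83 to 0.72 on the log2 scale, but 0 were called, while the median standard error rose from 0.18 to 0.20, and the contrast of both drugs with control and DMSO called 382 probes without a block, 24 with it and 0 with slide and row as a joint block. The same probes were picked on these arrays, so part of the kept change may be selection.

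The third pattern is the level of SAPD21854_1, higher in APAP and CBZ than in control and DMSO. Slide batch is argued against, as the log2 difference taken within slides was 1.29 against 1.41 over all arrays, positive in each of 8 pairs of drug and comparator on a slide, with an exact two-sided permutation p of 0.000446, the smallest that 2240 relabellings can give, for a probe picked for its change. Adjusted over all probes, the contrast of both drugs with control and DMSO stood at 1.26 with slide as a block (limma adjusted p = 0.00870), although single comparisons with that block missed the threshold, with 1.33 for APAP against control (adjusted p = 0.20), 1.07 for CBZ against control (adjusted p = 0.320) and 1.46 for APAP against DMSO (adjusted p = 0.0537), each from fewer arrays. A trend with probe level and GC content is argued against by a difference of 1.35 after its removal. As an explanation, 1 array far from the others is argued against by the separation of all arrays. The 10 APAP and CBZ arrays lay at -0.45 or higher, the 10 control and DMSO arrays at -0.96 or lower. The smallest difference with any array left out was 1.33, which adds nothing, as that separation was already known. Slide and row on the slide together stay open, as with both as a joint block the contrast went from 1.41 with a standard error of 0.158 to 1.25 with one of 0.190 (unadjusted p = 6.00e-06) and missed the threshold over all probes (adjusted p = 0.0623), a lost call that is no evidence for them, and neither they nor a difference between tanks, which the labels do not give, can be ruled out.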

How the results depend on the processing

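Without slide 2, slide 2 or 3 alone, slide and row as a joint block, no scaling, cyclic loess with GC trend removed, and the intensity trend were chosen after seeing the data. Counts are of probes past the threshold, and where no cause is given the cause was not tested. Slide as a block gave 0 for APAP and CBZ against control, APAP and AT against DMSO, APAP and CBZ against AT, and the 5 groups. Slide and row together gave 0 for the same ones except CBZ against AT, with 1. Slide as a random block (correlation 0.0516) gave 1 for APAP and 47 for CBZ against control, 0 for AT against DMSO, 254 and 593 for APAP and CBZ against AT, and 154 for the 5 groups. Without slide 2, with 20 arrays, these were 1 for APAP and 0 for CBZ against control, 1 for CBZ against DMSO, 11 and 72 against AT, and 2 for the 5 groups. Slide 3 alone gave 3 for DMSO, 0 for APAP, 0 for CBZ and 209 for AT against control (198 higher, 11 lower), 5, 1 and 47 for APAP, CBZ and AT against DMSO, and 411 (48 higher, 363 lower) and 74 (8 higher, 66 lower) for APAP and CBZ against AT. Slide 2 alone gave 0 for AT against control.

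Normexp gave 0, 2 and 0 for APAP, CBZ and AT against control, 0 for APAP and AT against DMSO, 2 and 3 for APAP and CBZ against AT, and 2 for the 5 groups. The median log2 difference of all probes was then 0.43 for DMSO against control, in place of -0.07, and -0.50 for CBZ against DMSO. It was 0.12 for CBZ against AT with quantile normalization and -0.48 for AT against control with no scaling. With normexp SAPD22030_1 stood at -0.17, SAPD24427 at -0.32, SAPD04273_1 at -0.20 and SAPD18721_1 at -0.59, reversed in sign. No scaling gave 0 for APAP, CBZ and AT against control and for APAP and AT against DMSO, 15 for APAP against AT and 20 for the 5 groups. Quantile normalization gave 0 for APAP and AT against DMSO, 1407 and 1947 for APAP and CBZ against AT, and 709 for the 5 groups. Cyclic loess with the GC trend removed gave 130 and 0 for CBZ and AT against control, 0 for AT against DMSO, 1146 and 1497 against AT, and 757 for the 5 groups. The deposited table gave 394, 361 and 0 for APAP, CBZ and AT against control, 5 and 5 for APAP and AT against DMSO, 1686 and 1982 against AT, and 1054 for the 5 groups.

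Array weights gave 565, 969 and 164 for APAP, CBZ and AT against control, 341, 680 and 25 against DMSO, 1 for APAP against CBZ, 1560 and 2594 against AT, and 2439 for the 5 groups. The 2 groups alone gave 1, 1, 255 and 0 for DMSO, APAP, CBZ and AT against control, 0 for APAP and AT against DMSO, and 0 and 378 against AT. Control and DMSO together gave 20, 33 and 8 for APAP, CBZ and AT. No filter gave 1 and 20 for APAP and CBZ against control, 0 for AT against DMSO, 270 for APAP against AT and 151 for the 5 groups, with more probes tested. Probes well above background on all arrays gave 120 and 6 for APAP and AT against control and 3 for AT against DMSO, with 7751 tested. The intensity trend gave 6 for AT against control and 3 for AT against DMSO. With the controls split, APAP and CBZ shared 0 probes, from fewer arrays per comparison and fits of 2 groups alone. A fold of at least 1.5 moved no count by over 1.5 times.

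Replicate number as a block gave 1 and 35 for APAP and CBZ against control, 1 and 0 for CBZ and AT against DMSO, and 148 for the 5 groups. The numbers do not pair the samples: 50 pairs with the same number had a median correlation of 0.0285, from -0.542 to 0.621, and 2 of 25 arrays correlated best with their own number. With 1 array left out, counts ran from 1 to 105 for APAP, 6 to 59 for CBZ and 0 to 16 for AT against control, 0 to 4, 0 to 2 and 0 to 9 for APAP, CBZ and AT against DMSO, 116 to 1388 and 220 to 1585 for APAP and CBZ against AT, and 116 to 513 for the 5 groups. DMSO against control and APAP against CBZ stayed at 0.

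The named probes were refitted in 488 cases, of which 221 kept direction and side of the threshold, 263 kept direction only and 4 reversed. SAPD21854_1 in APAP against control kept both in 20 of 25, with log2 differences from 1.27 to 1.71 and adjusted p from 0.000318 to 0.536. Planned gene list tests were not run, because no probe was given a gene name. Signal over background limits probes that were dim in a group to bounds.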

Other observations

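Of the 13605 probe names, 730 end in AS, and for 295 of these both that probe and another of the same number were kept. The log2 differences of the 2 probes of a pair correlated across pairs at r = 0.377 for CBZ against AT and 0.224 for APAP against AT. The AS probes were well above background on all arrays for 21.4% of pairs and their partners for 58.6%. Only 1 of the 730 pairs is an exact reverse complement.

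For 30 sequences, the array carried the same probe under 2 names. For the 26 pairs among them that were kept, the median absolute log2 difference between the spots of an array was 0.08. Probes with at least 1 forward reading frame free of stop codons were called between CBZ and AT for 749 of 8557, and those without for 157 of 1826 (Fisher's exact test, odds ratio 1.02, p = 0.855).

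SAPD21854_1 had a log2 level of -0.99 ± 0.50 (SD, n = 5) in AT. Its log2 difference from control there was 0.51 (limma adjusted p = 0.551), and APAP and CBZ were above AT by 1.08 (adjusted p = 0.0147) and 0.84 (adjusted p = 0.0277). With slide as a block 0 probes differed in either comparison with AT, so both calls were lost. Of the AT arrays, 3 lay on slide 2, which held no APAP or CBZ array.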
